A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

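Gene expression was measured in the above-ground tissue of 5-day-old rice seedlings of the cultivar Nipponbare. Wild-type seedlings and transgenic Ubi::OsYHB seedlings, which carry a constitutively active allele of the red light receptor phytochrome B under the maize Ubiquitin promoter, were raised on MS medium at 28 °C either in darkness or under continuous red light of 50 µmol per square metre per second. Per the labels, harvest fell in the subjective morning, and dark-grown seedlings were handled under dim green light. The design has 4 groups with 2 arrays each. Per the labels, the arrays of a group are biological replicates. In the OsYHB groups, replicate 1 is line 1, with 41-fold overexpression of the transgene, and replicate 2 is line 9, with 23-fold overexpression.

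Per the labels' protocols, total RNA was amplified and biotin-labelled with a 3' IVT kit and hybridised to Affymetrix arrays. The deposited table holds 1 intensity per probe set and array on a linear scale. Per the submitters' processing notes, RMA, GCOS and limma were used, with no version, role or order given. The background model, the summarisation settings and any centring are not given in the sources used here. The values have the shape of a table already normalized between arrays, and no further normalization was applied in the results as reported. The median intensity was 20.4 and 20.5 in the wild-type dark arrays, 20.6 and 20.4 in the wild-type red light arrays, 20.9 and 20.9 in the OsYHB dark arrays and 20.8 and 20.7 in the OsYHB red light arrays. Values have no detection call, so a low intensity is not shown to be above background, and a fold change of a dim probe set is compressed by background. For arrays the number of arrays limits the precision.

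The deposited intensities were converted to log2 before testing. Of 57381 probe sets, 123 Affymetrix control probe sets were left out, and 57258 were tested. The table of probe genes, which follows GEO's platform annotation, gave 1 gene for 22436 of these probe sets, several for 95 and none for 34727, which stay unnamed here. The 22436 probe sets cover 17905 genes, all of which were found in the RefSeq gene table, and 2458 of them have a name other than a locus or clone number. A gene was represented by its probe set with the highest mean over all 8 arrays. No pair of arrays held identical values.

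Group means were fitted with limma 3.58.1 in R 4.3.3 to all 8 arrays, so that the 4 groups share an estimate of the spread. The empirical Bayes step had no trend, with 4 residual and 4.27 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 57258 probe sets of each comparison. A probe set was called at an adjusted p below 0.05. The 6 comparisons were red light against dark in wild type, OsYHB against wild type in darkness, red light against dark in OsYHB, OsYHB against wild type in red light, the light by genotype interaction (the red light response of OsYHB minus that of wild type), and OsYHB in darkness against wild type in red light. A further fit compared line 1 with line 9 over both light conditions, with the replicate number of the wild-type arrays as a second term. Tables were handled with pandas 2.3.3 and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

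Replicate number stands for the same transgenic line in both OsYHB groups and so pairs those arrays. In wild type it is a number only. The deviations of the arrays from their group means had a correlation across probe sets of 0.145 between the OsYHB groups and of 0.093 between the wild-type groups. Between genotypes, where the numbers pair nothing, it was 0.003 and -0.169 for wild-type dark with OsYHB dark and red, and 0.078 and -0.172 for wild-type red with OsYHB dark and red. The block has 1 replicate term for both genotypes, although only the lines give the number a meaning. The fit with replicate as a block was run beside the fit without it, and the blocked value is given where it changed a call or moved a count of calls by over 1.5 times.

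The shift of 21 gene lists was tested with camera in limma, with a preset correlation between genes of 0.01, and p-values were adjusted over the 126 tests of 21 lists in 6 comparisons. The lists hold 524 distinct genes, 1 probe set per gene. They cover photosynthetic light reactions, carbon fixation and photorespiration, chlorophyll synthesis, chlorophyll breakdown, carotenoid and plastid isoprenoid synthesis, the cytosolic ribosome, light signalling, the circadian clock, expansins and xyloglucan enzymes, auxin, gibberellin, jasmonate, ethylene, phenylpropanoids, cellulose and wall matrix, cell division, heat shock, defence and oxidative genes and aquaporins. A further pair of lists marks other tissue, namely root genes and seed storage or late embryo genes. The lists had been planned by gene description. As the tables pair genes with names only, the lists were rebuilt from gene names before any fold change was seen. This added the aquaporin and chlorophyll breakdown lists, merged antenna and photosystem genes and dropped the plastid ribosome list. Where a gene product works was not checked, so the cytosolic ribosome list may hold plastid proteins. The comparisons, tests, thresholds and alternatives not described here as added later were fixed before the data were examined. Of the 126 list tests, 35 were called, and none of the 35 held when the correlation was estimated from the residuals, where the smallest adjusted p was 0.544. That setting rests on 4 residual degrees of freedom and was not run on simulated data. Its power is unknown, so a missing call under it does not show that a list is unshifted. Fry, which tests a list against no change, held 22 of the 35 and lost 13. It gave the light reaction list an adjusted p of 0.00189 in wild-type red light and in OsYHB darkness. Each called list had a median, a mean and a test of the same sign.

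The rule for the genes named in the text had 3 parts in each comparison. It took the phytochrome genes, then up to 8 called genes with the largest rise and 8 with the largest fall among those with an informative name, no cross-hybridising (_x_at) probe set and no overlap between the arrays of both groups, and then up to 2 called members of each list with the largest change. An informative name was read as one other than a locus or clone number. For the interaction, the red minus dark differences of all pairs of arrays had not to overlap. The names PORA, PORB, GLO3, GLO4, PSY3, AMT1, AMT2-1, JAZ2, GLN2, NIA1, SPX2, Nramp1, BHLH063, IRT1 and YSL15, where they stand outside this rule, were chosen after their values were seen, and so were all genes described by single arrays in the other observations.

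Both tests were tested on simulated data. In 10 simulated tables with 2000 changed probe sets in all, the fit of red light against dark in wild type recovered 3.13% of changes of 0.5 on the log2 scale, 77.3% of changes of 1 and 99.7% of changes of 2, and 7.21% of its calls were unchanged probe sets. The corresponding shares for OsYHB against wild type in red light were 2.39%, 76.9% and 99.5%, with 10.9% of calls unchanged. For the interaction they were 0.149%, 16.9% and 97.3%, with 13.3% unchanged. For OsYHB in darkness against wild type in red light they were 3.13%, 76.9% and 99.5%, with 9.48% unchanged. These error shares lie above the nominal level. The 2000 changed probe sets, over 10 tables of 57258, were a small share. In the data 9.73% were called in wild-type red light and 17% in OsYHB darkness. As the adjustment depends on the share of changed probe sets, recovery in the data can differ from these values. No change was planted for OsYHB against wild type in darkness or for red light in OsYHB. The number of simulated tables was raised from 1 to 10 after a run with 1 table. None of 126 null list tests was called, and a planted list had an adjusted p of 1.46e-48. The simulated probe sets varied independently of each other. The null list tests thus do not show how often lists of correlated genes would be called.

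Alternatives were quantile normalization, median centring, leaving out the lowest tertile of probe sets by mean intensity or those with a mean log2 below 6, a trended and robust prior, fits on the arrays of the groups compared, the replicate block, a 2-fold or a stricter threshold, 1 probe set per gene, leaving out probe sets ending in _x_at or _s_at, and leaving out each array in turn. For the lists they were an estimated correlation, fry, the mean of a gene's probe sets and the block. Leaving out the 64 probe sets for reporter and marker sequences was added after seeing the data. Genome coordinates are not used here.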

Results

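The data are 8 expression arrays of rice seedlings, with 2 arrays for each of wild type in darkness, wild type in red light, OsYHB in darkness and OsYHB in red light. The question of the design is what a constitutively active phytochrome B does to the seedling transcriptome without light and with it, next to the response of wild type to red light. Replicate arrays had a correlation of log2 intensity of 0.992 in wild-type dark, 0.996 in wild-type red light, 0.995 in OsYHB dark and 0.994 in OsYHB red light. The median standard deviation between replicates on the log2 scale was 0.133, 0.095, 0.101 and 0.093 in the same order. The first principal component held 54.5% of the variance and set the wild-type dark arrays, at -102.5 and -83.35, apart from the other 6 arrays, which lay between 19.12 and 39.83.

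**Figure D1:**
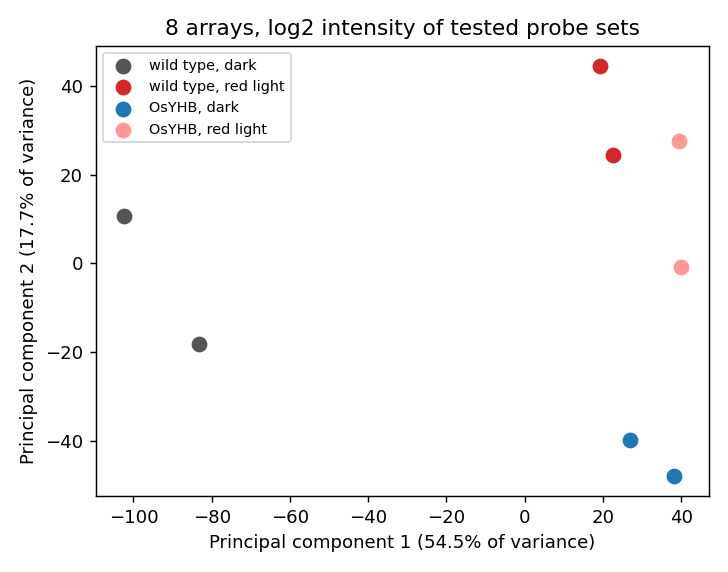
Principal component 1 (54.5% of variance) against principal component 2 (17.7%) of log2 intensities, in arbitrary score units, with 1 point per array and 2 arrays per group. The wild-type dark arrays lie at -102.5 and -83.35 on component 1 and the other 6 arrays between 19.12 and 39.83.

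PHYA, the gene of the light-labile phytochrome, was highest in wild-type darkness, at a mean log2 intensity of 11.64 ± 0.22 (SD, n = 2). It was lower in wild-type red light (10.45 ± 0.04), OsYHB darkness (10.21 ± 0.06) and OsYHB red light (10.11 ± 0.04). PHYA fell by 1.19 on the log2 scale in wild-type red light (SE 0.13, limma adjusted p = 0.000989) and by 1.43 in OsYHB darkness (SE 0.13, adjusted p = 0.00033). PHYB was not called in either comparison, with log2 changes of -0.26 (adjusted p = 0.509) and -0.27 (0.396), and neither was PHYC, with -0.15 (0.543) and -0.21 (0.288). The array's PHYB probe set did not follow the transgene, and where its probes lie relative to the transgene's transcript is unknown here, so it checks nothing about the labels. A probe set for a reporter or marker sequence had log2 intensities of 13.18, 12.9, 13.26 and 13.02 in the OsYHB arrays and between 2.85 and 3.02 in the wild-type arrays, which matches the genotype labels.

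**Figure D2:**
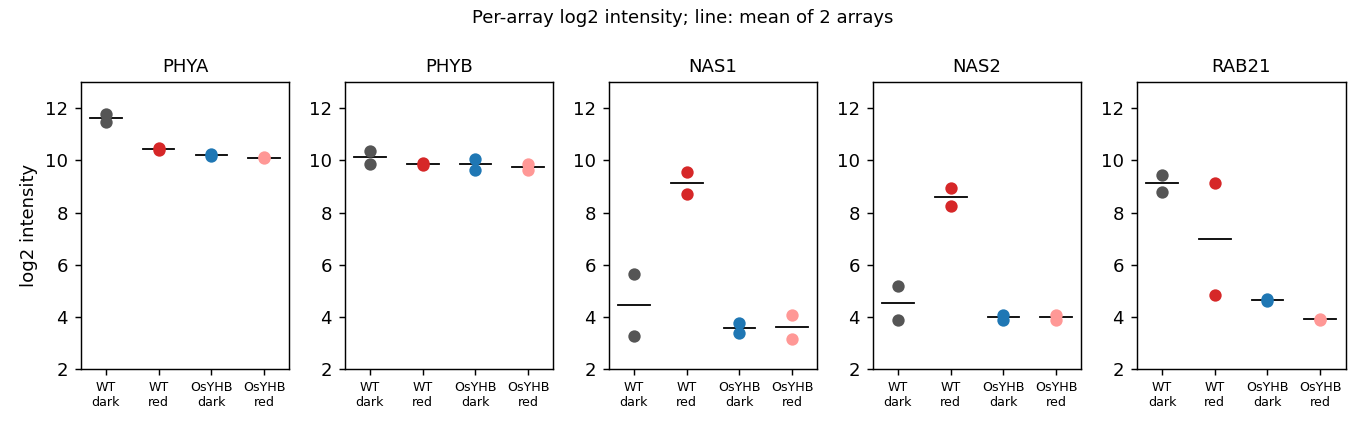
Log2 intensity of PHYA, PHYB, NAS1, NAS2 and RAB21, with 1 point per array and a line at the mean of the 2 arrays of each group. PHYA had a mean of 11.64 in wild-type darkness and of 10.45 or less in the other groups, while RAB21 lay at 4.84 and 9.14 in the wild-type red light arrays.

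In wild-type seedlings red light raised 12 of 17 genes of the photosynthetic light reactions and lowered 19 of 60 auxin genes. The shifts of both lists were called at a preset correlation, and not with an estimated one (adjusted p = 0.544 and adjusted p = 0.937 with an estimated correlation). Among named genes the largest rises included BURP16 (log2 4.79, SE 0.51), the nicotianamine synthase genes NAS1 (4.70, SE 0.68) and NAS2 (4.09, SE 0.38), the beta-glucosidase gene BGLU22 (4.65, SE 0.36) and PDX12 (4.39, SE 0.29). The chitinase gene Cht11 rose by 4.27, CFBP1, which encodes a cytosolic fructose-1,6-bisphosphatase, by 4.13, and the nicotianamine aminotransferase gene NAAT1 by 3.75. ILL3, an auxin conjugate hydrolase gene, fell by 6.93 on the log2 scale (SE 0.29, limma adjusted p = 1.7e-05), and the transporter gene ABCG45 (-4.19), the pectin methylesterase inhibitor gene PMEI8 (-4.17), the homeobox gene HOS9 (-3.97) and the lipid transfer protein gene LTP-2 (-3.96) fell as well. Further falls were those of the allene oxide synthase gene AOS4 (-3.79), the chitinase gene Cht1 (-3.78) and the auxin-conjugating GH3.2 (-3.60). All values are means of 2 arrays against 2. The largest changes of probe sets without a gene name were falls of -9.29 and -6.84 and rises of 8.19 and 7.20.

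Of 17 genes of the photosynthetic light reactions, 12 rose and none fell (13 rose when adjusted over the list alone), among them the chlorophyll a/b-binding protein gene RCABP69 (2.28) and the ferredoxin-NADP reductase gene LFNR1 (1.90). The list shift had a camera adjusted p = 6.35e-11, and an adjusted p = 0.544 with an estimated correlation. Of 12 carbon fixation and photorespiration genes, 8 rose (9 when adjusted over the list alone), led by the glycolate oxidase genes GLO5 (2.83) and GLO1 (2.03), with a camera adjusted p = 8.12e-08 and an adjusted p = 0.544 with an estimated correlation. Of 15 chlorophyll synthesis genes, 9 rose and 1 fell (11 and 1 when adjusted over the list alone), at a camera adjusted p = 2.02e-06 and an adjusted p = 0.55 with an estimated correlation. The magnesium chelatase subunit genes CHLH (2.15) and CHLI (1.45) rose, and the member that fell was PORA (-1.15), a protochlorophyllide oxidoreductase gene. In the carotenoid and plastid isoprenoid list 8 of 12 genes rose (9 when adjusted over the list alone), among them the phytoene synthase gene PSY2 (2.15) and CLA1 (1.48), at a camera adjusted p = 9.8e-06 and an adjusted p = 0.544 with an estimated correlation. Of 5 chlorophyll breakdown genes 3 rose, the same number as when adjusted over the list alone, among them RCCR1 (1.00) and the gene listed under both names CAO and Lls1 (2.07), at a camera adjusted p = 0.0104 and an adjusted p = 0.544 with an estimated correlation. In the clock list 3 of 8 genes rose (4 when adjusted over the list alone), PCL1 by 1.80 and PRR37 by 1.12, at a camera adjusted p = 0.00709 and an adjusted p = 0.544 with an estimated correlation.

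In the auxin list 19 of 60 genes fell and 2 rose (25 and 3 when adjusted over the list alone), including IAA20 (-2.37), with a camera adjusted p = 0.00492 and an adjusted p = 0.937 with an estimated correlation. Among root genes 8 of 21 rose and none fell (8 rose and 1 fell when adjusted over the list alone), at a camera adjusted p = 0.0195 and an adjusted p = 0.937 with an estimated correlation. Those that rose serve iron, ammonium, potassium and nitrate uptake, such as NAS1, NAS2 and the ammonium transporter genes AMT1 (2.34) and AMT2-1 (2.05). The silicon transporter genes Lsi1 and Lsi2 and the Casparian strip gene CASP1 were not called. Without wild-type dark replicate 2 the root list had an adjusted p of 0.336, and with fry, which tests a list against no change, of 0.139.

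The remaining lists were not called in wild-type red light as designed. Of them, fry called heat shock (adjusted p = 0.00796), aquaporins (0.035) and expansins (0.0377) lower, and no other. Expansins, heat shock, the ribosome and cell division were each called in a fit without 1 array. Expansins and xyloglucan enzymes had 2 of 31 genes lower (5 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.0825), namely EXP1 (-2.94) and EXP8 (-2.31). Of 45 heat shock genes 13 fell and 2 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0542), and CLPB1 fell by 2.81 and HSF02 by 2.69. Of 36 jasmonate genes 4 fell and 3 rose (7 and 4 when adjusted over the list alone; camera adjusted p = 0.486), with the lipoxygenase gene CM-LOX1 up by 3.69. Of 39 defence and oxidative genes 7 fell and 5 rose (11 and 8 when adjusted over the list alone; camera adjusted p = 0.986). Of 25 aquaporin genes 4 fell and 2 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 0.124), with OsPIP2;7 up by 2.85 and TIP1 down at -2.51. Of 46 cellulose and wall matrix genes 5 fell and 1 rose (11 and 4 when adjusted over the list alone; camera adjusted p = 0.133), among them GT43C (-0.88) and CSLE1 (0.71). Of 14 gibberellin genes 3 fell and 2 rose (7 and 2 when adjusted over the list alone; camera adjusted p = 0.595), including GA20OX2 (-1.20) and KAO (0.85). Of 11 ethylene genes 2 fell, also when adjusted over the list alone (camera adjusted p = 0.767), ACO1 (-1.22) and ERS2 (-0.81). Of 20 phenylpropanoid genes 3 rose and 2 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.369), including CAD6 (-1.84) and HCT3 (1.04). Of 11 light signalling genes 4 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.231), with GLK1 up by 1.18. Of 24 seed storage and late embryo genes 2 fell, also when adjusted over the list alone (camera adjusted p = 0.932), PXG (-2.37) and Dhn1 (-0.90). The cytosolic ribosome list had 1 of 24 genes higher, CL27 (0.55), also when adjusted over the list alone (camera adjusted p = 0.391). CL27 entered that list by its name alone, so a plastid rather than cytosolic product was not excluded. The cell division list had 0 of 49 both ways (camera adjusted p = 0.969).

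In all, limma called 5570 probe sets in wild-type red light, 2944 higher and 2626 lower, which is 9.73% of those tested, with a median absolute log2 change of 0.90. By gene, 1608 were higher and 1456 lower. The count was 2604 without wild-type red replicate 1, 2386 without wild-type red replicate 2 and 3329 on the arrays of both groups alone. Lower calls outnumbered higher ones without wild-type dark replicate 2 (2840 higher and 3060 lower) and with 1 probe set per gene (1796 and 1995). Of the 49 called genes the naming rule took, 8 lost their call without 1 array (adjusted p from 0.0584 to 0.168), with the wild-type red arrays, replicate 1 or 2, or a wild-type dark array left out. These are GT43C, CSLE1, PCL1, CL27, ERS2, GA20OX2, KAO and HCT3. On the arrays of both groups alone GT43C (0.0515), CL27 (0.0693) and ERS2 (0.055) lost it.

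In darkness OsYHB seedlings had 12 of 17 light reaction genes higher and 30 of 60 auxin genes lower than wild type. Both list shifts were called at a preset correlation, and not with an estimated one (adjusted p = 0.544 and adjusted p = 0.937 with an estimated correlation). PDX12 (log2 5.12, SE 0.29), CFBP1 (4.28, SE 0.13), BGLU22 (3.82, SE 0.36), the aquaporin gene OsPIP2;7 (3.49, SE 0.29) and the MADS-box gene MADS56 (3.48, SE 0.32) had the largest rises among named genes. GLO5 (3.26), GLT2 (3.04) and the nitrate reductase gene NIA1 (2.84) followed. The largest falls among named genes were those of ILL3 (-7.18, SE 0.29, limma adjusted p = 1.48e-05), the dehydrin gene RAB21 (-4.48, SE 1.07, adjusted p = 0.025), the oxophytodienoate reductase gene OPR4 (-4.46, SE 0.54), GH3.2 (-4.37) and the late embryogenesis gene LEA19 (-4.27, SE 1.12). HOS9 (-4.24), ABCG45 (-4.03) and LTP-2 (-3.91) fell as they did in wild-type red light. Of the probe sets without a gene name, reporter sequences left out, the largest rise was 7.39 and the largest falls -8.66 and -7.08.

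Of 17 light reaction genes 12 rose and none fell, also when adjusted over the list alone, with LFNR1 up by 2.20 and RCABP69 by 2.19 (camera adjusted p = 1.05e-09, adjusted p = 0.544 with an estimated correlation). Of 12 carbon fixation and photorespiration genes 9 rose and 2 fell (10 and 2 when adjusted over the list alone), with GLO1 up by 2.43 and the glycolate oxidase genes GLO3 (-0.56) and GLO4 (-0.57) down (camera adjusted p = 1.97e-07, adjusted p = 0.544 with an estimated correlation). GLO3 had an adjusted p of up to 0.157 and GLO4 of up to 0.166 where single arrays were left out, among them wild-type dark replicate 1 and OsYHB dark replicate 2. Of 15 chlorophyll synthesis genes 9 rose and 1, PORA (-1.0), fell (12 and 1 when adjusted over the list alone), with CHLH up by 1.49 and the glutamyl-tRNA reductase gene GluTR by 1.22 (camera adjusted p = 1.24e-06, adjusted p = 0.55 with an estimated correlation). Of 12 carotenoid and plastid isoprenoid genes 8 rose and 1 fell (9 and 2 when adjusted over the list alone), with PSY2 up by 2.53, PSY1 by 1.28 and PSY3 down at -1.26 (camera adjusted p = 0.000149, adjusted p = 0.544 with an estimated correlation). PSY3 had an adjusted p of 0.0591 without OsYHB dark replicate 2. Of 5 chlorophyll breakdown genes 4 rose and 1 fell, also when adjusted over the list alone, with the gene named CAO and Lls1 up by 1.24 and the stay-green gene SGR at -1.34 (camera adjusted p = 0.00847, adjusted p = 0.544 with an estimated correlation). In the clock list 3 of 8 genes rose and 1 fell, also when adjusted over the list alone, PCL1 by 2.23 and CCA1, also named LHY, at -0.97 (camera adjusted p = 0.0301, adjusted p = 0.578 with an estimated correlation). The clock list had an adjusted p of 0.0919 without wild-type dark replicate 2 and of 0.071 without OsYHB dark replicate 2.

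Auxin genes fell in 30 of 60 cases and rose in 1 (34 and 2 when adjusted over the list alone), including IAA20 (-3.20), at a camera adjusted p = 0.000578 and an adjusted p = 0.937 with an estimated correlation. Cellulose and wall matrix genes fell in 16 of 46 cases (17 fell and 2 rose when adjusted over the list alone), including BC1L9 (-1.32) and CSLA7 (-0.90), at a camera adjusted p = 0.0352 and an adjusted p = 0.937 with an estimated correlation. Expansins and xyloglucan enzymes fell in 8 of 31 cases (15 when adjusted over the list alone), including EXP1 (-3.45) and EXP8 (-2.28), at a camera adjusted p = 0.0412 and an adjusted p = 0.937 with an estimated correlation. Without wild-type dark replicate 1 the adjusted p was 0.144 for the cellulose list and 0.111 for the expansin list, and without OsYHB dark replicate 1 it was 0.0845 for the cellulose list. With the mean of a gene's probe sets it was 0.0508 for the cellulose list and 0.0711 for the expansin list.

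Jasmonate genes fell in 12 of 36 cases and rose in 3 (19 and 4 when adjusted over the list alone; camera adjusted p = 0.124), with AOS4 at -3.83. Of 45 heat shock genes 14 fell and 6 rose (18 and 9 when adjusted over the list alone; camera adjusted p = 0.708), with HSP16.9A at -2.96 and CLPB1 at -2.84. Of 39 defence and oxidative genes 13 fell and 5 rose (15 and 5 when adjusted over the list alone; camera adjusted p = 0.564), with Cht1 at -3.68 and the germin-like gene GER1 at -3.29. Of 25 aquaporin genes 7 fell and 1 rose (8 and 1 when adjusted over the list alone; camera adjusted p = 0.369), with TIP3 at -2.71. Of 14 gibberellin genes 4 fell and 2 rose (5 and 2 when adjusted over the list alone; camera adjusted p = 0.837), with GA20OX2 at -1.78 and GA20OX3 at -1.42. Of 11 ethylene genes 3 fell, also when adjusted over the list alone (camera adjusted p = 0.51), among them the ACC oxidase gene ACO1 (-1.68) and the receptor gene ERS2 (-0.99). Of 20 phenylpropanoid genes 4 rose and 4 fell (6 and 6 when adjusted over the list alone; camera adjusted p = 0.42), with 4CL2 up by 1.88 and CAD6 at -1.99. Of 11 light signalling genes 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.215), with CRYD, a DASH-type cryptochrome gene, up by 2.32. Of 24 seed storage and late embryo genes 6 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.584). Of 21 root genes 2 rose, also when adjusted over the list alone (camera adjusted p = 0.347), AMT2-1 by 2.34 and AMT1 by 1.31. Of 49 cell division genes 3 fell (0 when adjusted over the list alone; camera adjusted p = 0.1), including ORC1 (-0.74) and ORC5 (-0.67). The cell division list was called lower in the fits without wild-type dark replicate 1 or OsYHB dark replicate 1. Of 24 genes in the cytosolic ribosome list 2 rose (1 when adjusted over the list alone, camera adjusted p = 0.879), CL27 by 0.74 and CL18 by 0.47. Both entered the list by name alone, and plastid products were not excluded. Of the lists that camera did not call here, fry called heat shock (adjusted p = 0.0143), ethylene (0.0228) and aquaporins (0.043) lower, and no other.

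In all, limma called 9715 probe sets in OsYHB darkness, 4406 higher and 5309 lower, which is 17% of those tested, with a median absolute log2 change of 0.75. By gene, 1907 were higher and 3099 lower. The count was 5469 without OsYHB dark replicate 1, 3647 without OsYHB dark replicate 2, 4872 on the arrays of both groups alone and 6105 of 17905 with 1 probe set per gene (2096 higher and 4009 lower). The direction with more calls turned with the setting, to 4453 higher and 4278 lower after quantile normalization, 2611 and 2261 on the arrays of both groups alone, 2832 and 2637 without OsYHB dark replicate 1, 2072 and 1575 without OsYHB dark replicate 2, 1776 and 1267 with a 2-fold change and 2186 and 1728 at an adjusted p below 0.01. Of the 52 called genes the naming rule took, 11 lost their call without 1 array (adjusted p from 0.0526 to 0.206). They are RAB21, LEA19, TIP3, ORC1, ORC5, BC1L9, SGR, CCA1, CL18, GA20OX3 and AMT1, and OsYHB dark replicate 2 was the array without which all 11 lost it. RAB21 had an adjusted p of up to 0.12 and LEA19 of up to 0.154 without 1 array. With the replicate block ORC5 had an adjusted p of 0.0592, CL18 of 0.0601 and GLO4 of 0.0548. On the arrays of both groups alone TIP3 (0.0521), ORC1 (0.0591), ORC5 (0.0975), CCA1 (0.0705) and CL18 (0.116) lost their call, after quantile normalization BC1L9 (0.0538) and CL18 (0.053), and with a trended and robust prior RAB21 (0.111) and LEA19 (0.136).

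**Figure D3:**
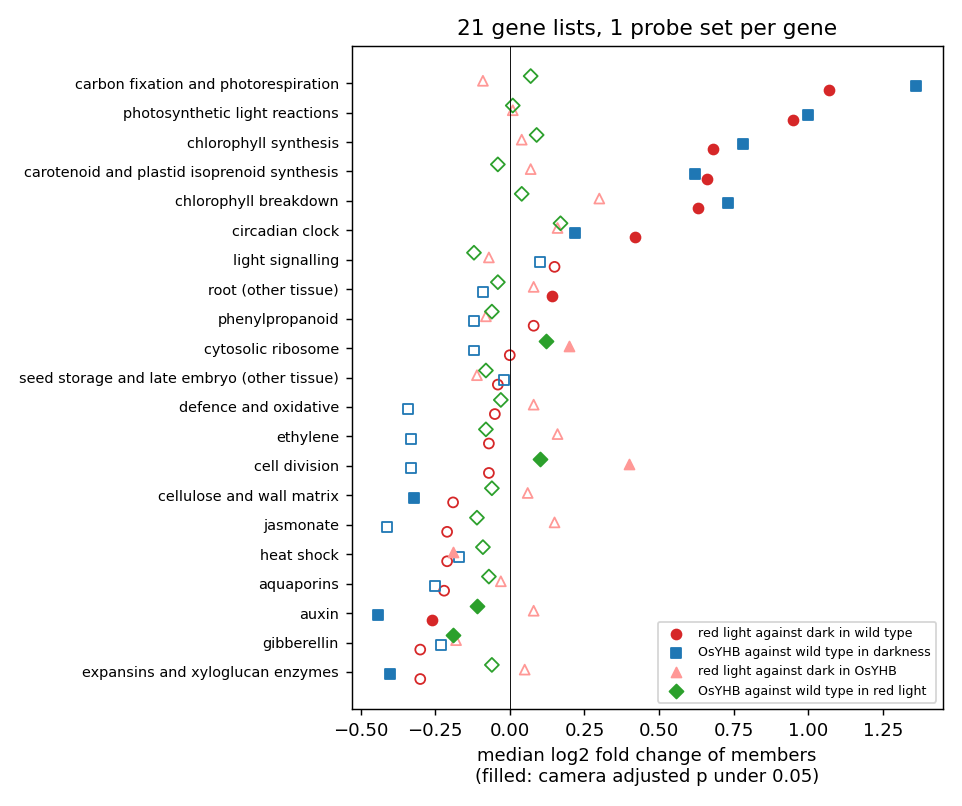
Median log2 fold change of the members of 21 gene lists (horizontal axis) in 4 comparisons, with 1 symbol per list and comparison and filled symbols where the camera adjusted p, at a preset correlation, is below 0.05. The light reaction list had a median of 0.95 in wild-type red light and of 1.00 in OsYHB darkness, but of 0.01 for red light in OsYHB.

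The responses to red light and to the allele overlapped. Probe sets called in both numbered 4442, of which 2347 were higher in both, 2089 lower in both and 6 opposite. Independent lists of these sizes would share 227 higher and 243 lower probe sets. Calls in OsYHB darkness alone numbered 5273 and in wild-type red light alone 1128, without a test of the difference, and this order turned without OsYHB dark replicate 2 (946 and 2024). Without OsYHB dark replicate 1 the calls in OsYHB darkness alone were 2226, and those in red light alone were 233 and 370 without wild-type red replicate 1 and 2. The log2 fold changes had a correlation across probe sets of 0.797. In 100 tables simulated without group differences, wild-type dark arrays included and shared by both comparisons, it was 0.502 (0.479 to 0.524). The covariance was 0.229 against a simulated 0.0158, a difference of 0.213. The simulated tables had a mean of 0.03 probe sets called in both. The simulated probe sets varied independently of each other, so deviations that many probe sets of an array share were left out. The simulated values thus do not bound what shared controls alone could give. The control group of 2 arrays cannot be split into parts of 2, so part of the excess may come from the shared controls. With a different wild-type dark array for each comparison the overlap was 2827 or 3427 probe sets, of which 102 or 24 were opposite, and the correlation was 0.556 or 0.703. It was 2371 without wild-type red replicate 1, 2016 without wild-type red replicate 2 and 2701 without OsYHB dark replicate 2.

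**Figure D4:**
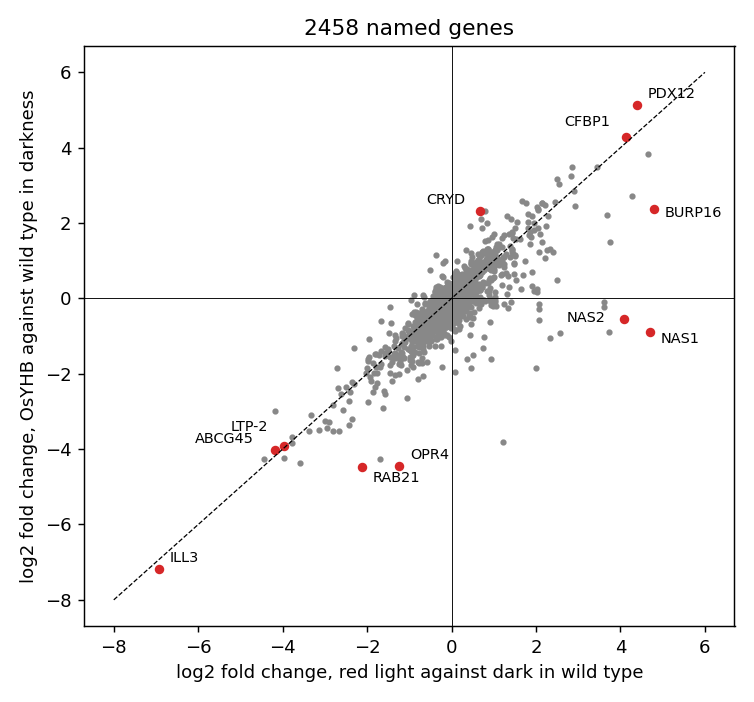
Log2 fold change of red light against dark in wild type (horizontal axis) against that of OsYHB against wild type in darkness (vertical axis) for 2458 named genes, 1 point per gene, with the line of equal change dashed. ILL3 lies at -6.93 and -7.18 and CFBP1 at 4.13 and 4.28, near the line, while NAS1 and NAS2 rose in red light, by 4.70 and 4.09, and were not called in OsYHB darkness.

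The direct comparison of OsYHB in darkness with wild type in red light asks where the allele and red light differ. NAS1 (-5.59, SE 0.68), NAS2 (-4.63, SE 0.38), the metal transporter genes Nramp1 (-4.63, SE 0.44) and COPT1 (-2.52, SE 0.26) and NAAT1 (-2.25, SE 0.30) were lower in OsYHB darkness, as was BHLH063 (-3.38, SE 0.26), an iron-related transcription factor gene. The phosphate-related SPX2 (-2.31), sfr2 (-1.18) and the expansin-like EXLA4 (-0.86) were lower too. CRYD (1.64, SE 0.13), the small heat shock gene HSP24.1 (1.51, SE 0.15) and 4CL2 (1.16, SE 0.14) were higher. The 3 phytochrome genes were not called, with log2 differences from -0.24 to -0.02. Limma called 111 probe sets, 40 higher and 71 lower. The carbon fixation list was higher (0 of 12 called, also when adjusted over the list alone; camera adjusted p = 0.0243), and so was the heat shock list (1 of 45 higher, 2 when adjusted over the list alone; camera adjusted p = 0.015). These had an adjusted p = 0.937 and an adjusted p = 0.578 with an estimated correlation. The auxin list (0 of 60 called, 4 lower when adjusted over the list alone; camera adjusted p = 0.00394) and the cell division list (0 of 49 called, also when adjusted over the list alone; camera adjusted p = 0.00706) were lower, each with an adjusted p = 0.937 with an estimated correlation. Without wild-type red replicate 1 the adjusted p was 0.0722 for carbon fixation, 0.0722 for heat shock and 0.057 for cell division, and without OsYHB dark replicate 2 it was 0.204, 0.125 and 0.38. With the mean of a gene's probe sets carbon fixation had 0.0693, and fry gave 0.312 for carbon fixation, 0.254 for heat shock, 0.136 for auxin and 0.394 for cell division. The count of 111 was 1 without wild-type red replicate 2, 28 without wild-type red replicate 1, 26 and 11 without OsYHB dark replicate 1 and 2, 192 without either wild-type dark array, 178 without either OsYHB red array and 232 on the arrays of both groups alone. All 12 named genes lost their call without wild-type red replicate 2 or OsYHB dark replicate 2, with adjusted p of up to 0.26. With the replicate block 24 probe sets were higher and 50 lower, NAAT1 had an adjusted p of 0.0637 and EXLA4 of 0.0812. With 1 probe set per gene NAS1 had 0.0558 and NAAT1 0.0682, with a trended and robust prior NAS1 had 0.0973 and EXLA4 0.0524, NAAT1 had 0.053 without the lowest tertile of intensity, and EXLA4 had 0.0507 after quantile normalization and 0.0589 on the arrays of both groups alone. The jasmonate list was not called as designed (0 of 36 called, 2 lower when adjusted over the list alone; camera adjusted p = 0.0519), and was lower with the replicate block (0.0468), with the mean of a gene's probe sets (0.0479), without OsYHB dark replicate 2 (0.0296) and without OsYHB red replicate 1 (0.00884) or 2 (0.00859).

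For red light on top of the allele few probe sets were called. The small heat shock gene HSP24.1 fell by 1.57 on the log2 scale in OsYHB (SE 0.15, limma adjusted p = 0.0457). PHYA, at a further -0.10 (adjusted p = 0.772), the other phytochrome genes and PORA, at a further -1.11 (adjusted p = 0.0815), were not called. Of 49 cell division genes 0 were called (4 higher when adjusted over the list alone), and the list was higher at a median of 0.40 (camera adjusted p = 2.14e-05, adjusted p = 0.937 with an estimated correlation). The cytosolic ribosome list was higher at a median of 0.20 (0 of 24 called, also when adjusted over the list alone; camera adjusted p = 0.00706, adjusted p = 0.937 with an estimated correlation). The heat shock list was lower at a median of -0.19 (1 of 45 lower, 5 when adjusted over the list alone; camera adjusted p = 0.000138, adjusted p = 0.544 with an estimated correlation). The ribosome list had an adjusted p of 0.194 without OsYHB dark replicate 2 and of 0.189 without OsYHB red replicate 1. With fry the adjusted p was 0.247 for cell division, 0.338 for the ribosome and 0.0519 for heat shock. Limma called 6 probe sets, 2 higher and 4 lower. The 2 called rises, of probe sets without a gene name, were 4.81 and 4.30. Of 57258 tested, 8365 had an unadjusted p below 0.05, more than unchanged probe sets would give on average. Few calls here thus do not show few changes. With the replicate block, which here pairs the arrays of each line, 2 were called, 1 higher and 1 lower. The count was 94 without OsYHB red replicate 1 (84 higher and 10 lower), 11 without either wild-type dark array, 0 without either wild-type red array and 3 and 0 without OsYHB dark replicate 1 and 2, and 61 with a trended and robust prior. HSP24.1 had an adjusted p of 0.138 and 0.214 without OsYHB dark replicate 1 and 2, 0.181 without OsYHB red replicate 2 and 0.075 without either wild-type red array. It had 0.0569 with the replicate block, 0.0515 after quantile normalization, 0.0643 without the lowest tertile of intensity, 0.0762 on the arrays of both groups alone and 0.0617 with 1 probe set per gene.

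In red light few probe sets were called between the genotypes. NAS2 was lower in OsYHB by 4.63 on the log2 scale (-4.63, SE 0.38, limma adjusted p = 0.0219), and SPX2 was lower as well (-2.07, SE 0.19, adjusted p = 0.0258). SPX2 was also called lower in OsYHB in darkness (-1.86, adjusted p = 0.000484), and not called for red light in wild type (0.45, adjusted p = 0.195). It lay at 4.79 to 5.29 in the OsYHB arrays and at 6.64 to 7.32 in the wild-type arrays, in both light conditions. PHYA stood at -0.34 and was not called (adjusted p = 0.631). The cell division list (median 0.10, camera adjusted p = 0.021) and the ribosome list (median 0.12, camera adjusted p = 0.00881) were higher, and the auxin list (median -0.11, camera adjusted p = 0.00706) and the gibberellin list (median -0.19, camera adjusted p = 0.0352) were lower, with 0 members of each called, also when adjusted over the list alone. These had an adjusted p = 0.937 with an estimated correlation, and the gibberellin list an adjusted p = 0.544 with an estimated correlation. Leaving out wild-type red replicate 2 or OsYHB red replicate 2 gave 0.193 and 0.196 for cell division and 0.161 and 0.196 for gibberellin. Leaving out OsYHB red replicate 1 gave 0.362 for the ribosome and 0.0537 for auxin, and leaving out wild-type red replicate 1 gave 0.0625 for auxin. Fry gave 0.758 for cell division, 0.645 for the ribosome, 0.399 for auxin and 0.087 for gibberellin, which had 0.0508 with the mean of a gene's probe sets. Alternatives also gained calls. Heat shock was lower with the mean of a gene's probe sets (camera adjusted p = 0.0371) and in some fits without 1 array. The jasmonate, seed storage, expansin, cellulose and defence lists were each lower in a fit without 1 array. In the fit as designed the jasmonate list had a mean log2 change of -0.32. Limma called 11 probe sets, 5 higher and 6 lower, of which 2 were reporter probe sets. Of 57258 tested, 4353 had an unadjusted p below 0.05, more than unchanged probe sets would give on average, so further differences may have been missed. With the replicate block 18 were called, 6 higher and 12 lower. The count was 40 without either wild-type dark array, 7 and 1 without wild-type red replicate 1 and 2, 4 without either OsYHB dark array and 22 on the arrays of both groups alone. Without OsYHB red replicate 1 there were 8 higher and 2 lower. NAS2 and SPX2 both lost their call without either wild-type red array, either OsYHB dark array or OsYHB red replicate 2, with adjusted p up to 0.258, and NAS2 also without OsYHB red replicate 1 (0.0704). Both had 0.0904 with 1 probe set per gene, and SPX2 had 0.131 on the arrays of both groups alone.

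The interaction asks whether the response to red light differed between genotypes. Genes that red light raised more in wild type than in OsYHB had negative interactions, such as PDX12 (-4.73), CFBP1 (-4.12) and BGLU22 (-3.99), and genes that it lowered more in wild type had positive ones, such as ILL3 (6.53), ABCG45 (4.39) and GH3.2 (4.16). Over the 2944 probe sets higher in wild-type red light, the median red light change was 1.02 in wild type and 0.01 in OsYHB. Over the 2626 lower ones it was -0.78 and -0.08. As these probe sets were chosen by their change in wild type, the wild-type medians can be enlarged by that choice. Limma called 2414 probe sets, 878 positive and 1536 negative. The count was 1377 and 809 without wild-type red replicate 1 and 2, 979 without OsYHB dark replicate 2 and 1258 and 1130 without OsYHB red replicate 1 and 2. Of 49 called genes that the naming rule took, 20 lost their call without 1 array, with adjusted p from 0.05 to 0.191.

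Line 1 and line 9 differed at 42 probe sets, 23 higher and 19 lower in line 1, over both light conditions. LOC4344865 was higher in line 1 by 6.59 on the log2 scale (SE 0.23, limma adjusted p = 0.000542) and LOC4338553 by 3.91 (SE 0.13, adjusted p = 0.000542). As line 1 is replicate 1 and line 9 replicate 2 in both OsYHB groups, a difference of line is also one of replicate number. The same fit called 3 probe sets between wild-type replicates 1 and 2. It had 2 residual degrees of freedom. An unadjusted limma p below 0.05 was found for 2649 probe sets between the lines and for 3641 between the wild-type replicates. Over all probe sets the lines thus did not stand out from replicates. The count of 42 was 6 without either OsYHB red array, 16 without any other array and 23 without the lowest tertile of probe sets by mean intensity.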

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

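The tests of scaling, of phytochrome activity, of a signal ceiling, of noise, of a response already present in darkness, of root tissue and of a single array were chosen only after the result was seen.

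The light by genotype interaction differed from 0 at 2414 probe sets, so the response to red light differed between wild type and OsYHB there. The count was 1377 and 809 without wild-type red replicate 1 and 2, 979 without OsYHB dark replicate 2 and 1258 and 1130 without OsYHB red replicate 1 and 2. Negative log2 interactions, for genes whose red light change was lower in OsYHB than in wild type, were -4.73 for PDX12, -4.66 for NAS1, -4.12 for CFBP1, -4.09 for NAS2, -3.99 for BGLU22, -3.27 for MADS56, -3.23 for BURP16, -3.20 for NIA1 and -3.08 for OsPIP2;7. Called members of the photosynthesis and pigment lists had interactions of -2.98 (GLO5), -2.39 (GLO1), -2.24 (PSY2), -1.38 (PSY1), -2.19 (RCABP69), -2.02 (LFNR1), -1.90 (CHLH), -1.48 (GluTR), -1.77 (the gene named CAO and Lls1) and -1.03 (NYC1). Other negative interactions were those of AMY1.3 (-2.15), CRYD (-1.57), CIGR2 (-1.26), 4CL2 (-1.18), the phototropin gene listed as Osnph1b (-1.13) and PRR37 (-0.74).

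Positive interactions, for genes whose red light change was higher in OsYHB than in wild type, were 6.53 for ILL3, 4.39 for ABCG45, 4.16 for GH3.2, 4.10 for HOS9, 4.10 for the metallothionein gene MT-1-4b, 3.53 for LTP-2, 3.52 for OsCASPL1D1 and 3.42 for the phytosulfokine gene PSK2. Further positive interactions of single list members were 3.33 (Cht1), 3.22 (GER2), 3.20 (EXP1), 2.81 (IAA20), 2.78 (OPR5), 2.67 (HSP16.9A), 2.62 (CLPB1), 2.23 (EXP8), 2.23 (TIP1), 2.15 (AOS4), 1.96 (PXG), 1.68 (CAD6), 1.46 (ACO1), 0.98 (ORC1) and 0.79 (CSLE2), and PHYA had 1.09. PHYA had an adjusted p between 0.0591 and 0.0805 in the 5 fits without 1 array in which it lost its call, and 29 of the 49 genes held in all fits except those with stricter thresholds. With the replicate block 4 calls ended, those of BURP16 (adjusted p = 0.0661), TIP1 (0.0764), ORC1 (0.0754) and PRR37 (0.0796). Other settings ended those of NAS1 (0.112), BURP16 (0.139), OPR5 (0.0666) and TIP1 (0.0519) with a trended and robust prior, TIP1 (0.0601) and ORC1 (0.0741) after quantile normalization, PRR37 (0.052) after median centring, and TIP1 (0.0512) and PRR37 (0.0528) without _x_at and _s_at probe sets.

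By list, the interaction was negative for the light reactions (11 of 17 negative, 12 when adjusted over the list alone; camera adjusted p = 1.03e-10), carbon fixation and photorespiration (8 of 12, 9 negative and 1 positive when adjusted over the list alone; 1.05e-07), chlorophyll synthesis (3 of 15, 10 when adjusted over the list alone; 1.52e-06), carotenoid and plastid isoprenoid synthesis (3 of 12, 8 negative and 1 positive when adjusted over the list alone; 0.000141) and chlorophyll breakdown (2 of 5, 4 negative and 1 positive when adjusted over the list alone; 0.00782). It was positive for auxin (12 of 60, 20 positive and 1 negative when adjusted over the list alone; 0.00491) and cell division (1 of 49, 0 when adjusted over the list alone; 0.0112). The estimated correlation ended all 7 calls, with an adjusted p = 0.544 with an estimated correlation for light reactions, carbon fixation, carotenoids and chlorophyll breakdown, 0.55 for chlorophyll synthesis and 0.937 for auxin and cell division. The cell division list had an adjusted p of 0.278 without wild-type dark replicate 2 and of 0.105 without OsYHB dark replicate 2, and of 0.307 with fry. The interaction was not called as designed for the other 14 lists, of which fry called expansins alone (positive, adjusted p = 0.043). Some of the 14, among them root genes, expansins, light signalling, the clock and jasmonate, were called in fits without 1 array. Members went both ways in the defence list (5 of 39 positive and 3 negative, 6 and 4 when adjusted over the list alone; camera adjusted p = 0.595), the heat shock list (8 and 3 of 45, 10 and 4 when adjusted over the list alone; 0.971) and the aquaporin list (1 and 1 of 25, also when adjusted over the list alone; 0.382). The adjusted p was 0.0675 for expansins (4 of 31 positive, 5 when adjusted over the list alone), 0.0845 for cellulose (1 of 46 positive, also when adjusted over the list alone), 0.344 for jasmonate (3 of 36 positive, 3 positive and 1 negative when adjusted over the list alone) and 0.68 for ethylene (1 of 11 positive, 2 when adjusted over the list alone). It was 0.0698 for the clock, 0.0737 for light signalling, 0.0878 for root genes, 0.248 for phenylpropanoids, 0.403 for seed storage, 0.51 for the ribosome and 0.784 for gibberellin.

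The wild-type dark arrays stood apart from the other 6, which underlies both large comparisons and the interaction. Were a shift of whole arrays left by the authors' scaling the cause, scaling again would have to remove most calls of OsYHB against wild type in darkness. At least 83.5% of them were called again after quantile normalization and after median centring. But the array medians already lay between 4.35 and 4.39 on the log2 scale, so centring could move little. The test thus cannot decide about distortions that the authors' normalization hid or made. The mean 3' minus 5' log2 signal of control genes was 2.96 and 2.89 in the wild-type dark arrays and 2.90 to 3.23 in the others, a mean difference of -0.12 over the 3 pairs with both ends above a log2 of 6, a limit set after the levels were seen. With 1 array within the range and 1 just below it, RNA quality cannot be told apart from the group on this measure. A candidate explanation is phytochrome activity, from light or from the allele, and this stays a hypothesis. That 12 light reaction genes were higher and none lower in OsYHB darkness is the list result given above, and so no separate test of it.

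Few probe sets were called for red light in OsYHB. Were a signal ceiling in the OsYHB dark arrays the cause, dimmer probe sets would still have responded. Yet over 2208 probe sets that rose in wild-type red light and lay below a log2 of 10 in OsYHB dark, the median change in OsYHB was 6.54% of that in wild type (0.07 against 1.03). Noisier OsYHB arrays would hide calls without shrinking the median of many changes, but that median was 1.16% of the wild-type one over the 2944 higher and 9.77% over the 2626 lower probe sets. The median replicate SD was 0.101 in OsYHB dark and 0.093 in OsYHB red against 0.133 in wild-type dark and 0.095 in wild-type red, and 290 and 501 against 788 and 231 probe sets differed 2-fold between replicates. Most of the response may already be present in dark-grown OsYHB seedlings, as the median change in OsYHB darkness was 62.9% to 90.6% of that in wild-type red light over the probe sets called in the latter, with a different wild-type dark array for each side. The direct comparison with wild-type red light called 53 of the 2944 higher and 13 of the 2626 lower probe sets, and its 111 calls in all fell to 1 without wild-type red replicate 2, so this stays a hypothesis.

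NAS1, NAS2, NAAT1, Nramp1 and BHLH063, known from iron acquisition and picked for their rise, were high in the wild-type red light arrays, while the iron uptake genes IRT1 (log2 change 0.14, limma adjusted p = 0.616) and YSL15 (0.06, 0.835) were not called there. Nramp1 and BHLH063 also stood higher in OsYHB red light than in OsYHB darkness, without a call. Nramp1 lay at 8.29 and 6.8 against 4.92 and 4.67, and BHLH063 at 7.82 and 7.14 against 5.18 and 5.12. For them an apparent rise is thus not particular to wild type. Root tissue in the wild-type red samples alone would raise other root genes over OsYHB red light alike. But 16 root genes other than those of iron had a median difference of -0.06 between wild type and OsYHB in red light (-0.72 to 0.15), against 1.88 for the 5 iron genes. Several of the 16 lie near the lowest intensities. Root tissue in both red light groups would cancel in this difference, so the values cannot decide about it. Of the 16, HAK1 lay at 8.56 and 7.48 in wild-type red and at 7.27 and 9.01 in OsYHB red. In the dark arrays it lay between 5.56 and 6.2. Lsi1 went the other way, at 8.88 to 8.97 in the red light arrays and 9.15 to 9.88 in the dark arrays. Of the 5, limma called NAS2 between the genotypes in red light (adjusted p = 0.0219) and not NAS1 (0.0822), NAAT1 (0.325), Nramp1 (0.491) or BHLH063 (0.518). For NAS1, NAS2 and NAAT1 the lower wild-type red array led the highest array of the other groups by at least 1.22 on the log2 scale. In each case this was more than the largest gap between replicates of that gene. The naming rule had already required no overlap with wild-type dark and OsYHB dark, and for NAS2 with OsYHB red, so those leads test nothing. Over OsYHB red, the lower wild-type red array of NAS1 stood at 8.73 against 4.05 and 3.14, and that of NAAT1 at 7.78 against 6.37 and 6.56. They show that both wild-type red arrays lay above both OsYHB red arrays. But both genes were picked with both wild-type red arrays clear of the dark groups. The 2 leads are thus no independent test of a single odd array. For Nramp1 and BHLH063 a single odd array stays open, as the lead (at least 0.46) lay within the gaps between replicates. So does a difference in metal nutrition between genotypes, which was not tested.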

How the results depend on the processing

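The setting without reporter probe sets was chosen after the data were seen and moved no count by over 1.5 times. No named gene or list result past its threshold, in the fit as designed or under an alternative, changed sign. The balance of higher and lower calls did turn, in 2 of 20 settings for red light in wild type (as to 2840 higher and 3060 lower without wild-type dark replicate 2), in 6 for OsYHB in darkness (as from 4406 and 5309 to 4453 and 4278 after quantile normalization), in 6 for red light in OsYHB (as from 2 and 4 to 84 and 10 without OsYHB red replicate 1), in 4 for OsYHB in red light (as from 5 and 6 to 8 and 2 without OsYHB red replicate 1), in 1 for OsYHB dark against wild-type red (1 and 0 without wild-type red replicate 2) and in 0 of 19 for the interaction. Quantile normalization and median centring kept all counts of calls within 1.5 times, and the share of higher calls moved by under 10 percentage points. A result not called in the fit as designed was compared by its call alone. The causes of the changes below were not tested, except that stricter thresholds give fewer calls by construction and that 1 probe set per gene leaves 17905 tests.

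For red light in wild type, 5570 calls became 3329 on the arrays of both groups, 2366 with a 2-fold change, 2530 at an adjusted p below 0.01 and 2386 to 5900 without 1 array. For OsYHB in darkness, 9715 became 4872 on the arrays of both groups, 6105 with 1 probe set per gene, 3043 with a 2-fold change, 3914 at the stricter threshold and 3647 to 9823 without 1 array. For red light in OsYHB, 6 became 1 without the lowest tertile of intensity, 12 above a mean log2 of 6, 61 with trend and robust prior, 0 on the arrays of both groups, 2 with the replicate block, 0 with 1 probe set per gene, 19 without _x_at and _s_at probe sets, 0 at the stricter threshold and 0 to 94 without 1 array. Beside these counts of 0, limma had 8365 probe sets with an unadjusted p below 0.05 in the fit as designed. For OsYHB in red light, 11 became 7 without the lowest tertile of intensity, 1 above a mean log2 of 6, 22 on the arrays of both groups, 18 with the replicate block, 0 with 1 probe set per gene, 1 at the stricter threshold and 1 to 40 without 1 array. For the interaction, 2414 became 795 at the stricter threshold and 809 to 3304 without 1 array. For OsYHB dark against wild-type red, 111 became 232 on the arrays of both groups, 42 with 1 probe set per gene, 21 at the stricter threshold and 1 to 192 without 1 array. For the lines, 42 became 23 without the lowest tertile of intensity and 6 to 16 without 1 array. The overlap of 4442 became 1802 with a 2-fold change, 2827 with a different dark array for each comparison and 2016 to 5006 without 1 array.

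Against 35 called list shifts there were 0 with an estimated correlation, 34 with the mean of a gene's probe sets (31 of them among the 35), 36 with the replicate block (all 35 and jasmonate), 29 with fry, which tests a list against no change (22 among the 35, with 13 lost and 7 gained), and 31 to 42 without 1 array (29 to 34 among the 35). The block changed no call of a comparison, list or named gene other than those given with it. Of 165 called named gene results, 106 held in all settings, 54 were lost without 1 array and 23 under another setting apart from the stricter thresholds. Without 1 array, the lone array of its group is assumed to vary like the other groups. Low intensities limit the data further, as no detection call is given.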

Other observations

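The comparisons below, and the tests on gene families, were chosen only after the result was seen.

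Some genes of diterpenoid phytoalexin synthesis, antimicrobial compounds of rice, were far apart in the replicates of OsYHB in red light, without a list fixed for them or a test. The log2 intensity of CPS2 was 2.98 in replicate 1 (line 1) and 7.36 in replicate 2 (line 9), that of CPS4 3.22 and 6.66, of CYP71Z7 3.51 and 7.47, of CYP701A8 3.28 and 7.53 and of CYP99A2 3.39 and 6.33. CYP99A3 (4.04 and 5.45) and CYP76M7 (3.07 and 5.08) were less far apart, CYP76M8 lay at 6.62 and 7.02, and CYP71Z6 went the other way, at 4.74 and 4.01. The pathogenesis-related PBZ1 lay at 8.15 and 12.04 and the chitinase gene Cht2 at 5.15 and 8.38 in the same arrays. Line 9 in darkness had CPS2 at 2.17, and the wild-type red light arrays had it at 7.0 and 4.96. None of these genes was called for red light in wild type, where CPS2 had a log2 change of 3.62 (limma adjusted p = 0.105).

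In the wild-type red light replicates RAB21 lay at 4.84 and 9.14, LEA19 at 3.39 and 7.84 and OsPM19L1 at 3.98 and 5.79, but Dhn1 at 8.95 and 8.99. In wild-type darkness RAB21 lay at 9.44 and 8.80. JAZ2, a jasmonate repressor gene, lay at 9.10 and 6.91 in wild-type darkness, 9.32 and 9.13 in wild-type red light, 2.94 and 5.42 in OsYHB darkness and 2.49 and 3.19 in OsYHB red light. Its change in OsYHB darkness was -3.82 (SE 0.84, limma adjusted p = 0.0179), with an adjusted p between 0.0693 and 0.0853 in the 4 settings that ended the call, among them those without wild-type dark replicate 1 or OsYHB dark replicate 1. The protochlorophyllide oxidoreductase genes moved apart, as PORA fell in wild-type red light (-1.15) and OsYHB darkness (-1.0) while PORB rose (0.86 and 0.81). The PORB probe set is of the cross-hybridising kind (_x_at), so related transcripts may add to its signal. PORB had an adjusted p between 0.0508 and 0.0789 in the settings that ended its calls, which were those without either wild-type red array or either OsYHB dark array and the fits on the arrays of both groups. NIA1 rose by 2.89 in wild-type red light and 2.84 in OsYHB darkness, and the plastid glutamine synthetase gene GLN2 by 1.02 and 1.28.

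Over 51 families of genes with a shared symbol, 5 of 306 camera tests had an adjusted p below 0.05, and none with an estimated correlation (smallest adjusted p = 0.998 with an estimated correlation). They were the auxin response factor family ARF (10 of 18 lower, adjusted p = 0.0468) and the IAA family (14 of 26 lower, 0.0378) in OsYHB darkness, HSP (lower, with 1 of 22 called, 0.0269) and the protein disulfide isomerase family PDIL (higher, with 0 of 11 called, 0.0378) for red light in OsYHB, and IAA (lower, with 0 of 26 called, 0.0349) in OsYHB darkness against wild-type red light.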
